A study of Arabidopsis thaliana with 9 samples.

How the data were processed

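RNA was sequenced from whole Arabidopsis seedlings of the accession Col-0, 2 weeks old and grown in hydroponic culture with 16 h light at 22 °C and 8 h dark at 18 °C, under 150 µmol m-2 s-1. The 9 libraries are 3 replicates each of the wild type (wt), clpp2-1 and clpp2-2. As deposited by the authors, the table holds expected_counts: estimated counts of reads per gene, rounded to whole numbers and not normalized before deposition, for 22254 genes whose counts over the 9 libraries sum to at least 10. The authors' notes name FastQC, Salmon 0.14.0, DESeq, DESeq2 and the build TAIR10, and the role of each is not given in the sources used here. Library totals lay close together, from 36043744 to 36477053, which leaves scaling before deposition possible. Intervals and floors of 3 counts per library cover counting error only, and these and other comparisons with counting error assume unscaled counts. Gene positions and products came from the TAIR10.1 annotation, which holds 22056 of the identifiers; the other 198 are organelle identifiers (118 mitochondrial, 80 plastid), which were named from fixed lists only.

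Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr left 20294 genes, 1960 were removed, TMM factors ran from 0.974 to 1.025, and 1 quasi-likelihood fit of all 9 libraries gave 4 contrasts, namely each line against the wild type, the mean of both lines against the wild type, and clpp2-2 against clpp2-1. The common biological coefficient of variation was 0.176, and the median log2 fold change of all genes was -0.001 in clpp2-1 and -0.012 in clpp2-2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of 1 contrast. Each standard error (SE) was the absolute log2 fold change over the root of the F statistic. The shares of counts from each organelle genome were compared by exact two-sided permutation tests in Python 3.11.15.

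The 32 gene lists hold 507 genes, of which 501 are in the table. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of 1 contrast, with a smallest list of 5 tested genes. Alternatives for the lists were a correlation estimated from the data and fry. The groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule names CLPP2, and then up to 12 higher and 12 lower genes called in both lines with all 6 mutant libraries beyond all 3 wild-type libraries and a mean of at least 1 CPM, ranked by the smaller change of the lines. It adds the 5 higher and 5 lower genes with the largest change per line and between the lines under the same criteria, up to 4 members per list by smallest adjusted p for the mean of both lines, and the genes within 10 positions of CLPP2.

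The alternatives were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block and only the groups compared. Others were library sizes without organelle genes, which were still tested, each library left out in turn and a 2-fold threshold. A library left out leaves 2 in its group, and the spread is pooled over groups. Removing library trends with GC content and exon length, leaving out wt 1 and clpp2-1 1, and the block with both trends removed were chosen after seeing the data. The trends were removed from the 20101 nuclear genes tested, and organelle genes received no such correction. Whether the numbers pair libraries is not stated, and was checked from their deviations from the genotype mean over 12677 genes. The correlations of same-numbered libraries across genes, which are not independent replicates, were 0.16, 0.133 and 0.115 between the wild type and clpp2-1, -0.009, 0.047 and 0.005 between the wild type and clpp2-2, and -0.174, 0.08 and -0.092 between the lines, so blocked values stand beside the results for clpp2-1. Differently numbered libraries gave -0.266 to 0.105 between the wild type and clpp2-1, and up to 0.185 between the lines. Pairing is therefore possible and not shown. In each group every pair of libraries differed by more than counting error (6.39 to 33.2 chi-square per gene).

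The tests were tested on simulated data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For clpp2-1 edgeR called 43.3, 76.1 and 90.9% of them, with 5.41% of its calls false, and for clpp2-2 49.3, 70.1 and 97.0%, with 5.88% false. DESeq2 had 29.0 and 24.3% false calls and limma-voom 4.79 and 5.26%. Nuclear copies of mitochondrial DNA were found with BLAST 2.17.0 as genes with at least 50% of exon bases matched at 95% identity or more. Tables were handled with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. The reads were not used here.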

Results

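RNA abundance was measured in whole Arabidopsis thaliana seedlings of 3 genotypes, with 3 libraries each: the wild type Col-0 and the knock-out lines clpp2-1 and clpp2-2. CLPP2 is the proteolytic subunit of the Clp protease of the mitochondrial matrix, and the series asks how the assembly of complexes encoded in the nuclear and the mitochondrial genome is coordinated without it. The deposited counts summed to 36273787, 36248488 and 36267401 in the wild-type libraries, to 36333790, 36332002 and 36369630 in clpp2-1, and to 36477053, 36043744 and 36363306 in clpp2-2. Each library held counts for 21459 to 21546 genes, and its 10 most abundant genes took 5.47 to 6.76% of the counts. Whether replicates came from separate cultures is not stated, so each p-value measures only the spread between these samples, which may be technical. Values are CPM (counts scaled to library size) as mean ± SD of 3 libraries, and a gene or list is said to have risen or fallen where its adjusted p was under 0.05. In every gene said below to have risen or fallen in 1 line, or to differ between the lines, all 3 libraries of the one genotype lay beyond all 3 of the other, as 10% of genes without changes do.

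CLPP2 transcripts were strongly reduced in both lines. CLPP2 (AT5G23140, chromosome 5, 7783673 to 7785547 in TAIR10.1, 2 exons) stood at 44.7 ± 1.83 CPM in the wild type (n = 3), at 5.56 ± 0.616 CPM in clpp2-1 and at 4.60 ± 0.0709 CPM in clpp2-2. In clpp2-1 this was 8.02-fold lower (log2 -3.00, SE 0.0833, adjusted p = 2.38e-06), and in clpp2-2 9.70-fold lower (log2 -3.28, SE 0.0849, adjusted p = 1.33e-06). CLPP2 did not pass the test between the lines (log2 -0.27, adjusted p = 0.119). The insertion sites are not stated, so the residual counts cannot be placed before or after them. Of the genes within 10 positions on either side, 19 were tested, and edgeR called 0 of them in either line. At an unadjusted p under 0.05 there were 1 in clpp2-1 and 6 in clpp2-2, limma-voom called 0, and DESeq2 called 0 and 4.

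The share of counts from the mitochondrial genome was higher in every mutant library than in any wild-type library. It was 0.0554 ± 0.00269% in the wild type, 0.0955 ± 0.0104% in clpp2-1 and 0.110 ± 0.00454% in clpp2-2 (SD, n = 3 each), which is 1.73 and 1.98 times the wild type. The exact two-sided permutation test gave p = 0.1 for each line, the smallest that 3 against 3 libraries allow, and p = 0.0119 for the 6 mutant against the 3 wild-type libraries, the smallest of 84 arrangements. Between the lines the share differed 1.15-fold, within what the exact test allows (p = 0.2). The plastid share was 0.397 ± 0.0361% in the wild type, 0.447 ± 0.0640% in clpp2-1 and 0.523 ± 0.0422% in clpp2-2 (n = 3 each). Its exact permutation p was 0.3 for clpp2-1, 0.1 for clpp2-2, 0.0714 for both lines together and 0.2 between the lines.

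**Figure D1:**
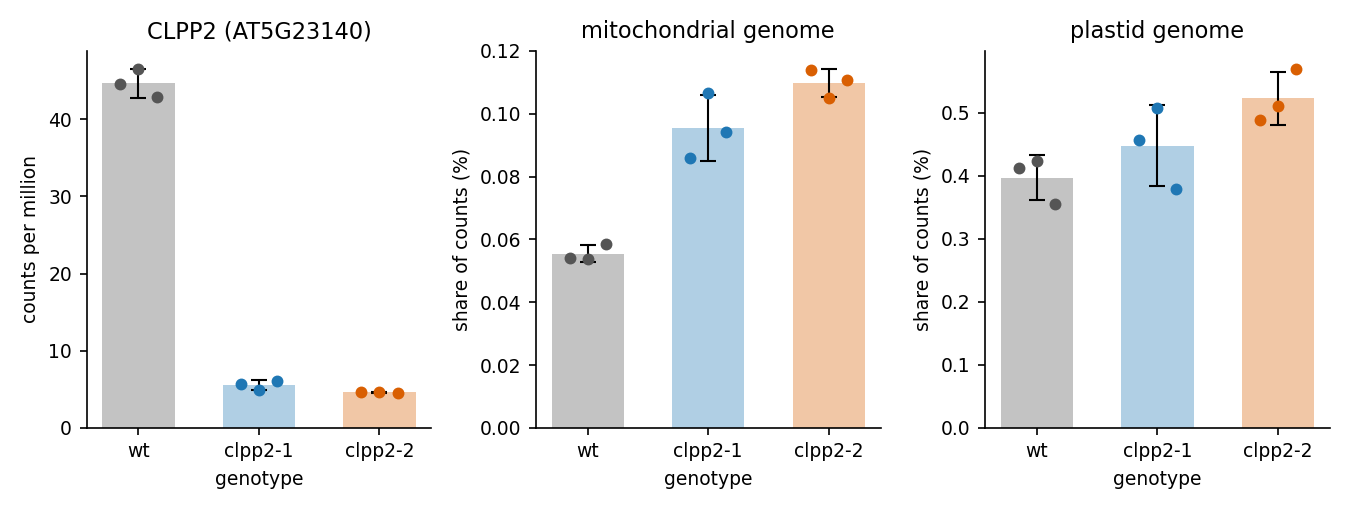
CLPP2 in CPM and the percent of counts from the mitochondrial and the plastid genome in wild type, clpp2-1 and clpp2-2; bars are means of 3 libraries, error bars the SD and points the libraries. CLPP2 fell from a mean of 44.7 CPM to 5.56 and 4.60 CPM, and the mitochondrial share was 0.0554% in the wild type against 0.0955% and 0.110% in the mutants.

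The comparison of clpp2-1 with the wild type asks what the loss of CLPP2 changed in the first line. The change lay mainly in the mitochondrial genome: 36 of 20294 genes tested changed, 31 higher and 5 lower, and 27 of the 36 were mitochondrially encoded, 26 of them higher. Among mitochondrially encoded genes with a named product, the ATP synthase genes atp8 and atp9 rose most. atp9, a subunit of the enzyme's membrane ring, rose from 13.7 ± 0.919 to 51.1 ± 7.44 CPM (3.74-fold, log2 1.90, SE 0.107, adjusted p = 0.000185). atp8 rose from 2.99 to 13.5 CPM (log2 2.17, SE 0.172, adjusted p = 0.00151). atp6-1 rose from 8.82 to 22.8 CPM (log2 1.37, SE 0.0731, adjusted p = 0.000185), and atp1 from 49.5 to 95.3 CPM (log2 0.95, adjusted p = 0.00293). The complex I identifiers nad7 (log2 1.10, adjusted p = 0.00293), nad1C (log2 1.22, adjusted p = 0.0196) and nad3 (log2 1.47, adjusted p = 0.0269) and the ribosomal gene rps12 (log2 1.34, adjusted p = 0.00769) also rose. nad1C is a part of nad1, whose other listed parts, nad1A and nad1B, were not called. Nor was atp6-2, listed apart from atp6-1. ccmC, a cytochrome c maturation gene, fell from 5.23 to 2.51 CPM (log2 -1.06, adjusted p = 0.0355).

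Mitochondrial identifiers without a name in the lists used here also rose in clpp2-1, among them, by the rule for named genes, ATMG00670 (log2 2.87), ATMG01020 (log2 2.77), ATMG01010 (log2 2.3), ATMG01090 (log2 2.14), ATMG01000 (log2 1.88), ATMG00040 (log2 1.64), ATMG00660 (log2 1.63), ATMG01200 (log2 1.61), ATMG01220 (log2 1.56), ATMG00030 (log2 1.49) and ATMG00500 (log2 1.49). Of the 9 nuclear genes that changed, 5 were higher and 4 lower, CLPP2 included. AT3G56210, an ARM repeat protein (chromosome 3, 20852380 to 20855610), fell from 136 ± 4.64 to 91.9 ± 1.99 CPM (log2 -0.57, SE 0.0406, adjusted p = 0.000893). AT5G01990, of the auxin efflux carrier family (chromosome 5, 377231 to 379911), fell from 24.3 ± 1.33 to 13.5 ± 0.969 CPM (log2 -0.85, SE 0.0764, adjusted p = 0.00308). AT2G07775 (chromosome 2, 3483035 to 3484062) rose from 1.51 to 3.95 CPM (log2 1.38, adjusted p = 0.0161). Its exon sequence matches mitochondrial DNA over 100% of its length. AT4G36850, a PQ-loop transmembrane protein (chromosome 4, 17353291 to 17356037), had no count in any wild-type library and 6.11 ± 2.23 CPM in clpp2-1. It was at least 74.2-fold higher against a floor of 3 counts per library (adjusted p = 0.0105, and 0.178 by limma-voom). AT3G09360, a cyclin and Brf1-like protein (chromosome 3, 2873412 to 2878591), stood at 3.32 ± 1.61 CPM in the wild type and had no count in clpp2-1. It was at least 40.7-fold lower (adjusted p = 0.0107, and 0.0754 by limma-voom). Both belong to 386 genes that were at 0 in some libraries and at 30 counts or more in every other. Of the 386, 4 followed a genotype, where random placement gives 2.64.

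Same-numbered wild-type and clpp2-1 libraries were more alike in their deviations than differently numbered ones, which does not show that they were paired. A fit with the number as a block called 23 genes in clpp2-1, or 24 with GC content and exon length of the nuclear genes corrected as well. With the block the call was lost for ccmC (adjusted p = 0.104), nad3 (0.0801), nad1C (0.0868), ATMG00500 (0.156), AT2G07775 (0.0571) and AT3G09360 (0.104). Without wt 1 there were 23 calls, and without wt 2 there were 63. ATMG01010 lost its call without wt 1 (adjusted p = 0.0527), ATMG00040 without wt 1 (0.0791), clpp2-1 2 (0.0531) or clpp2-1 3 (0.0563). ccmC lost it without any 1 of the 9 libraries (0.05001 to 0.219). nad3 lost it without any library but wt 2 (0.0588 to 0.123), and ATMG00500 without any but clpp2-1 1 and clpp2-1 2 (0.0523 to 0.113). nad1C lost it without wt 1, wt 3, any clpp2-1 library or clpp2-2 3 (0.05001 to 0.0961). AT2G07775 lost it without wt 1, wt 3, clpp2-1 2, clpp2-1 3, clpp2-2 1 or clpp2-2 3 (0.05001 to 0.0983).

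By gene group, the mitochondrially encoded subunits of complexes III, IV and V had the largest median and mean change of the lists called in clpp2-1. Of the 10 identifiers for mitochondrially encoded subunits of complexes III, IV and V, which count atp6-1 and atp6-2 apart, 5 rose (8 adjusted over the list alone). The list median was log2 0.73 (adjusted p = 1.14e-19; adjusted p = 0.161 with an estimated correlation). Of the 13 mitochondrially encoded complex I identifiers, which count parts of nad1, nad2 and nad5 apart, 3 rose (adjusted over the list alone, 6 rose and 2 fell). Their median was 0.28 (adjusted p = 5.38e-07; 0.603 with an estimated correlation). Of the 14 mitochondrially encoded ribosomal and cytochrome c maturation genes, 2 rose and 1 fell (adjusted over the list alone, 6 and 3), with a median of 0.11 (adjusted p = 0.0422; 0.605 with an estimated correlation). That call was lost with the block (adjusted p = 0.0741) and without wt 1 (0.0842), wt 2 (0.0747), wt 3 (0.0613) or clpp2-1 2 (0.282). None of the other calls in clpp2-1 held with an estimated correlation, where the adjusted p was 0.161 for carbon starvation and 0.605 or 0.718 for the rest.

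The mitochondrial dysfunction stimulon, nuclear genes that respond to impaired mitochondria, had a median of 0.15 (adjusted p = 0.00409; lost without wt 1, 0.439, and without clpp2-1 2, 0.0665). Mitochondrial import genes had a median of 0.10 (adjusted p = 0.00324; without wt 1, 0.0842; without clpp2-1 2, 0.110). Mitochondrial proteases and chaperones had a median of 0.05 (0.0283; without wt 1, 0.112; without clpp2-1 2, 0.282; without clpp2-1 3, 0.0501). Plastid-encoded photosystem genes had a median of 0.25 (0.00317; without wt 1, 0.0715; without clpp2-1 2, 0.280). The chloroplast Clp protease had a median of 0.07 (0.0305; without wt 1, 0.386; without wt 3, 0.497; without clpp2-1 2, 0.434). Phosphate starvation genes had a median of 0.23 (0.0107; without wt 1, 0.112; without wt 2, 0.215; without clpp2-1 2, 0.384; without clpp2-1 3, 0.0736). Nuclear-encoded subunits of complexes II to V had a median of 0.03 (0.0400; with the block, 0.0513). That call was lost without wt 1, wt 2, clpp2-1 2, clpp2-1 3 or any clpp2-2 library (0.0526 to 0.385). Iron deficiency genes had a median of -0.28 and a mean of -0.61 (0.00317), lost without wt 1 (0.203), the library whose mean deviation over this list was highest, at log2 0.82. Hypoxia genes had a median of -0.17 (0.000251; without clpp2-1 2, 0.0664), and carbon starvation genes -0.15, with a mean of -0.48 (0.000749, kept without any 1 library). Morning clock genes had a median of -0.12 (0.0400; lost without any library but wt 3, 0.0610 to 0.405). By mean deviation, the 3 clpp2-1 libraries lay beyond the 3 wild-type libraries for 4 of the 14 called lists, namely the 3 mitochondrially encoded lists and carbon starvation. Without wt 1, or without clpp2-1 2, 4 of the 32 lists were called in place of 14.

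The lists not called in clpp2-1 were nuclear-encoded complex I subunits (median 0.02, adjusted p = 0.395), mitochondrial RNA polymerase, splicing and editing factors (0.02, 0.263), the TCA cycle (0.05, 0.134), photorespiration (0.01, 0.890), and light-harvesting and Rubisco small subunit genes (0.04, 0.499). Nor were heat shock (-0.08, 0.712, with a mean of 0.12), salicylic acid and defence (-0.03, 0.403), jasmonate (0.10, 0.739), cold, drought and abscisic acid (-0.14, 0.189), and touch and handling (0.01, 0.839, with a mean of -0.02) called. The same held for evening clock (-0.09, 0.0927), antioxidant enzymes (0.01, 0.991), glucosinolate synthesis (-0.04, 0.467) and flavonoids (0.07, 0.189), and for senescence (0.15, 0.289), root markers (-0.14, 0.467, with a mean of 0.02) and floral markers (0.01, 0.354, where the test pointed down). Seed storage markers had a median of -3.25 (0.0730, and 0.0422 with the block). Seed storage RNA differed between libraries of one genotype. Its 8 listed genes summed to 102 CPM in wt 1 (95% exact Clopper-Pearson interval 99.2 to 106), 22.4 in wt 2 (20.8 to 23.9) and 0.276 in wt 3 (0.132 to 0.507). They summed to 12.3, 2.56 and 0.742 CPM in clpp2-1, and to 0.603, 1.03 and 1.07 CPM in clpp2-2. Without wt 1 and clpp2-1 1, which held the most seed storage RNA in their genotypes, 23 genes were called in clpp2-1, 727 in clpp2-2, 94 for the mean of both lines and 336 between the lines.

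The comparison of clpp2-2 with the wild type asks the same of the second line, in which far more genes changed. In clpp2-2 1116 genes rose and 928 fell (2044 of 20294), 382 of them by at least 2-fold. Of these, 50 were mitochondrially encoded (49 higher), 21 plastid-encoded (21 higher) and 1973 nuclear (1046 higher and 927 lower). atp9 rose from 13.7 ± 0.919 to 48.9 ± 2.42 CPM (3.58-fold, log2 1.84, adjusted p = 0.000103), and atp8 from 2.99 to 12.1 CPM (log2 2.01, adjusted p = 0.000677). atp6-1 rose from 8.82 to 24.5 CPM (log2 1.47, adjusted p = 4.13e-05), atp1 from 49.5 to 113.6 CPM (log2 1.2, adjusted p = 0.000222) and nad7 from 9.51 to 25.5 CPM (log2 1.42, adjusted p = 0.000205). ATMG00030 rose from 34.4 to 126.7 CPM (log2 1.88, adjusted p = 2.52e-05).

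Apart from CLPP2 and AT4G36850, the nuclear genes named here for the widest changes in clpp2-2 did not pass the test in clpp2-1. AT2G47780, of the rubber elongation factor family (chromosome 2, 19570040 to 19571034), rose from 8.15 ± 2.99 to 142.7 ± 12.1 CPM (log2 4.13, SE 0.286, adjusted p = 0.000218). It stood at 10.5 ± 3.34 CPM in clpp2-1. AT3G44006 (chromosome 3, 15796133 to 15796837) rose from 0.0829 ± 0.0742 to 8.67 ± 0.123 CPM (log2 6.66, adjusted p = 0.000131). QQS, an orphan gene linked to starch content, rose from 0.712 ± 0.623 to 19.8 ± 2.99 CPM (log2 4.80, SE 0.722, adjusted p = 0.00793). The Aux/IAA gene IAA20 rose from 0.155 ± 0.136 to 3.33 ± 0.702 CPM (log2 4.39, SE 0.744, adjusted p = 0.0123). LTP4, a lipid transfer protein gene (chromosome 5, 23924990 to 23925957), fell from 123.3 ± 24.8 to 13.2 ± 3.22 CPM (log2 -3.23, SE 0.247, adjusted p = 0.000368). AT3G02400, a forkhead-associated domain protein with 2 annotated transcripts, fell from 14.66 ± 1.15 to 0.820 ± 0.711 CPM (log2 -4.16, adjusted p = 0.00795). AT4G12510 fell from 2.08 to 0.151 CPM (log2 -3.76, adjusted p = 0.0254). That call was lost without wt 1 (0.0712), wt 3 (0.0629), clpp2-2 2 (0.0770) or clpp2-2 3 (0.0710). In AT1G73350, an ankyrin repeat protein with 7 annotated transcripts, every wild-type and clpp2-1 library was at 0. In clpp2-2 it stood at 4.39 ± 1.39 CPM, at least 53.2-fold higher than the wild type (adjusted p = 0.00392). AT1G72250, with a kinesin motor domain and 4 annotated transcripts, and AT3G54930, a regulatory subunit of protein phosphatase 2A with 3, were at 0 in every clpp2-2 library, at least 26.3-fold and 20.7-fold lower than the wild type (adjusted p = 0.00394 and 0.00792). AT4G36850 was at least 110-fold higher in clpp2-2 (9.06 ± 3.79 CPM, adjusted p = 0.00152). AT1G73350, AT1G72250 and AT4G36850 are among the 386 genes with counts of 0 in some libraries and at least 30 in every other, of which 97.4% have 2 or more annotated transcripts.

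Mitochondrially encoded gene groups rose in clpp2-2 as well. Of complexes III, IV and V, 8 of 10 members rose (9 adjusted over the list alone), with a median of 0.99 (adjusted p = 3.75e-11; 0.417 with an estimated correlation). Of the complex I list, 8 of 13 rose (10 adjusted over the list alone), with a median of 0.66 (adjusted p = 1.46e-06; 0.417 with an estimated correlation). Of the ribosomal and cytochrome c maturation list 7 of 14 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.55 (adjusted p = 6.72e-05; 0.417 with an estimated correlation). ccmC fell to 3.53 CPM (log2 -0.57, adjusted p = 0.0425), a call lost without any library but clpp2-1 2 (0.0532 to 0.129). In contrast to these, nuclear-encoded complex I subunits had a median of 0.06 (adjusted p = 0.0425; 0.647 with an estimated correlation), with 3 of 38 higher (adjusted over the list alone, 5 higher and 1 lower). The call was lost without wt 2 (0.0603), wt 3 (0.158), clpp2-2 1 (0.121) or clpp2-2 2 (0.0526). Nuclear-encoded subunits of complexes II to V had a median of 0.05 (adjusted p = 0.0131; 0.647 with an estimated correlation; without clpp2-2 1, 0.0975), with 1 of 42 higher.

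Plastid-encoded photosystem, light-harvesting, photorespiration and chloroplast Clp protease lists were also called higher in clpp2-2, and wt 2 overlapped the mutant in 3 of the 4. Plastid-encoded photosystem genes had a median of 0.48, with 4 of 13 higher (4 adjusted over the list alone; adjusted p = 0.000683). Its member psbC, a photosystem II antenna protein, rose by log2 0.60 (SE 0.0723, adjusted p = 0.00303). Light-harvesting and Rubisco small subunit genes had a median of 0.32, with 2 of 21 higher (2 adjusted over the list alone; adjusted p = 0.000627). Its member RBCS2B rose from 208.8 to 391 CPM (log2 0.91, SE 0.145, adjusted p = 0.0102). Photorespiration genes had a median of 0.32, with 2 of 14 higher (6 adjusted over the list alone; adjusted p = 0.00559). The chloroplast Clp protease had a median of 0.13, with 2 of 15 higher (4 adjusted over the list alone; adjusted p = 0.00302). For these 4 lists the adjusted p was 0.647 with an estimated correlation. The mean deviation of wt 2 lay above that of clpp2-2 1 for light-harvesting genes (0.200 against -0.042), photorespiration (0.078 against 0.072) and the chloroplast Clp protease (0.067 against 0.056), and the plastid-encoded list alone of the 4 kept all 3 libraries apart. Root markers had a median of -0.36 (adjusted p = 0.0253; 0.647 with an estimated correlation), with 17 of 18 below 0, and the call was lost without wt 3 (0.102). edgeR called 0 of the 18 root markers, 5 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0.

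Lists called lower in clpp2-2 were heat shock, glucosinolate synthesis and floral markers, besides root markers; by mean deviation only root markers kept all 3 libraries apart. The heat shock list had a median of -0.29, with 3 of 11 lower (5 adjusted over the list alone; adjusted p = 0.0133; 0.417 with an estimated correlation; without wt 2, 0.0706). Its member HSP90-1 fell (log2 -0.49, adjusted p = 0.0154), a call lost without wt 3 (0.0501), clpp2-2 2 (0.0747) or clpp2-2 3 (0.0648). Aliphatic glucosinolate synthesis had a median of -0.20, with 3 of 15 lower (3 adjusted over the list alone; adjusted p = 0.0120; 0.647 with an estimated correlation; without wt 3, 0.0610; without clpp2-2 1, 0.0936). Floral markers had a median of -0.97, with 2 of 5 lower (2 adjusted over the list alone; adjusted p = 0.0120; 0.417 with an estimated correlation; without wt 2, 0.0681). The floral organ gene SEP3 fell from 9.33 ± 0.971 to 3.41 ± 0.0400 CPM (log2 -1.45, adjusted p = 0.00102). The floral list's mean deviation was also low in wt 1, at log2 -0.71, against 0.66 and 0.73 in wt 2 and wt 3.

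Single members stood out in lists that were not called in clpp2-2. CAT2, a peroxisomal catalase, rose from 248.1 ± 2.16 to 531.7 ± 54.3 CPM (log2 1.10, SE 0.0801, adjusted p = 0.000297) in the antioxidant list (median 0.02, adjusted p = 0.579). SEN1, induced by darkness and starvation, rose from 11.1 ± 1.69 to 49.6 ± 2.85 CPM (log2 2.16, SE 0.213, adjusted p = 0.00123) in the carbon starvation list (median -0.02, adjusted p = 0.579). The cold-regulated genes COR15B and COR15A rose by log2 2.60 (2.11 to 12.8 CPM, adjusted p = 0.000514) and 1.03 (5.81 to 11.9 CPM, adjusted p = 0.00761) in a list with a median of 0.25 (adjusted p = 0.0630). The stress-induced transcription factor genes WRKY40 (log2 1.71, adjusted p = 0.00497) and ERF5 (log2 1.47, adjusted p = 0.00687) rose in the touch and handling list (median 0.18, adjusted p = 0.0833). The clock gene PRR9 fell (log2 -0.66, adjusted p = 0.00779) in the morning clock list (median -0.06, adjusted p = 0.723). The remaining lists were mitochondrial proteases and chaperones (median 0.14, adjusted p = 0.0577), the stimulon (-0.15, 0.330), RNA polymerase, splicing and editing (0.04, 0.877, with a mean of -0.003), import (0.08, 0.129) and the TCA cycle (0.01, 0.737). Also not called were iron deficiency (-0.18, 0.851), salicylic acid (-0.19, 0.154), jasmonate (-0.07, 0.859, with a mean of 0.002), hypoxia (-0.19, 0.851), evening clock (-0.07, 0.136), flavonoids (0.24, 0.467), phosphate starvation (-0.26, 0.177), senescence (-0.11, 0.928) and seed storage (-7.14, 0.0848).

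The count in clpp2-2 rested on several libraries: it was 783 without wt 1, 4242 without wt 2, 630 without wt 3, 1175 without clpp2-1 3, and 730, 502 and 604 without clpp2-2 1, 2 and 3. On the first principal component (35.8% of the variance) wt 2 lay at -0.89, near clpp2-1 2 at -1.27, while wt 1 and wt 3 lay at -19.8 and -20.7 and the clpp2-2 libraries at 20.1 to 21.5.

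**Figure D2:**
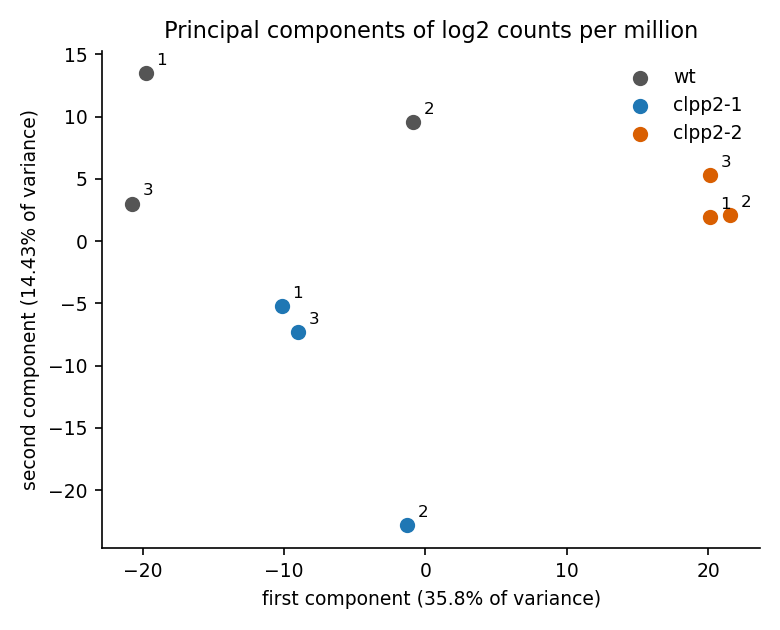
Position of the 9 libraries on the first (35.8% of the variance) and second (14.4%) principal components of log2 CPM; numbers are replicates. The clpp2-2 libraries lie together at 20.1 to 21.5 on the first component, and wt 2 lies at -0.89, apart from wt 1 and wt 3.

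What both lines share is asked by the genes called in each in the same direction. There were 33 such genes, 30 higher and 3 lower, of which 27 were mitochondrially encoded and 6 nuclear. Lists drawn independently would share 1.71 higher and 0.229 lower genes. That expectation treats genes as independent, while several of the 27 have neighbouring identifiers, such as ATMG01190 (atp1), ATMG01200, ATMG01210 and ATMG01220. With the replicate block in the clpp2-1 comparison 22 were shared, 18 of them mitochondrially encoded (18 higher) and 4 nuclear. Besides CLPP2, AT4G36850, AT3G56210 (109 ± 1.72 CPM in clpp2-2, log2 -0.32, adjusted p = 0.00388) and AT2G07775 (4.66 CPM, log2 1.62, adjusted p = 0.00148), the nuclear genes were scpl48 and AT4G26600, chosen here after their values were seen. scpl48 (AT3G45010), a serine carboxypeptidase-like gene, stood at 19.0 CPM in the wild type, 33.7 in clpp2-1 and 27.5 in clpp2-2 (log2 0.83 and 0.53, adjusted p = 0.00332 and 0.00639). AT4G26600, a putative methyltransferase, stood at 19.8, 42.2 and 35.6 CPM (log2 1.09 and 0.85, adjusted p = 0.0388 and 0.0150). Its clpp2-1 call was lost with the replicate block (adjusted p = 0.117) and without any library but clpp2-2 2 (0.0638 to 0.199). Its clpp2-2 call was lost without wt 3 (0.0598), clpp2-2 1 (0.05001) or clpp2-2 3 (0.0537). A single gene went opposite ways, AT2G05915, also chosen after its values were seen, at 6.77 CPM in the wild type, 15.8 in clpp2-1 and 3.20 in clpp2-2. Its clpp2-1 call was lost with the block (adjusted p = 0.0978) and without wt 3, any clpp2-1 library, clpp2-2 1 or clpp2-2 2 (0.0521 to 0.121).

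The mitochondrial genes did not rise alike. Over 116 mitochondrial genes tested, the mean change of both lines ran from log2 -1.27 to 3.00 with a median of 0.40, and 53 lay more than 3 SE from that median. ATMG00670 stood at 1.54 CPM in the wild type, 11.3 in clpp2-1 and 12.3 in clpp2-2 (log2 2.87 and 2.99, adjusted p = 0.00151 and 0.000368), and ATMG01090 at 8.29, 36.6 and 38.1 CPM (log2 2.14 and 2.2). cob, of complex III, and rps3, chosen here after their values were seen, showed changes of log2 0.006 and -0.21 in clpp2-1 and 0.24 and 0.11 in clpp2-2, none of which passed the test. Both lines were compared with the same 3 wild-type libraries, which cannot be split between them. In 50 simulations all 9 libraries were drawn gene by gene from the wild-type means, without changes, and both lines shared the 3 drawn controls. There edgeR called 0 genes in both lines, against 33 here. The draws hold no structure between libraries, so they cannot show what sharing the real wild-type libraries gives. The correlation of the changes across genes (0.361; genes are not independent replicates) was below that of the simulations (0.395 to 0.575). Their covariance (0.0612) lay within the simulations (0.0531 to 0.0890). So did the percent of equal sign among the 2044 genes with the smallest p in clpp2-2 (83.86 against 83.51 to 88.11). The count of 33 was 20 without wt 1, 57 without wt 2, 21 without clpp2-1 3 and 19 without wt 1 and clpp2-1 1.

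**Figure D3:**
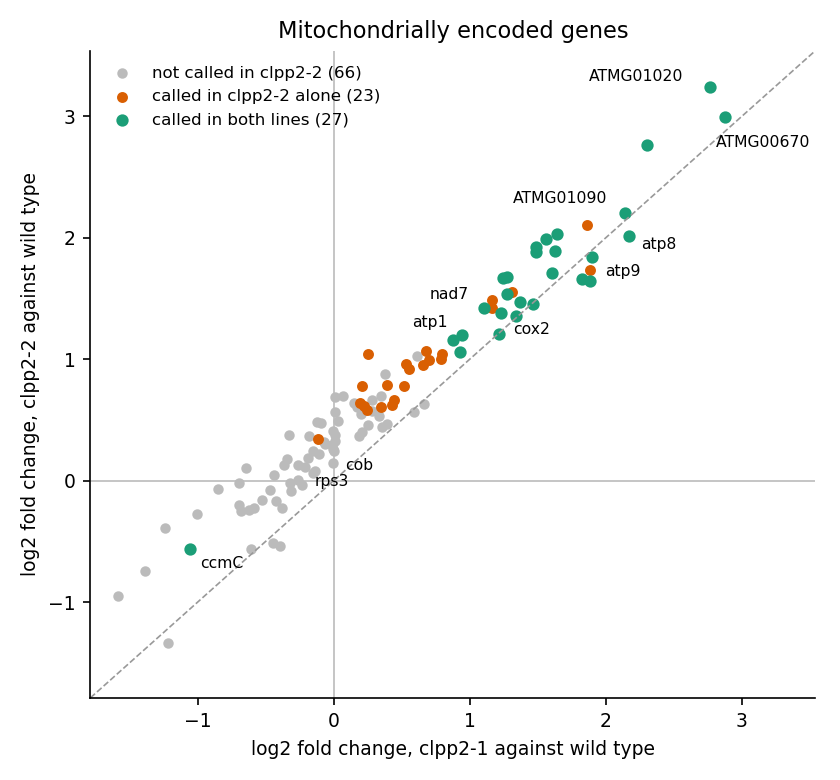
Log2 fold change against wild type of 116 mitochondrially encoded genes in clpp2-1 (horizontal axis) and clpp2-2 (vertical axis); 27 genes called in both lines are green, 23 called in clpp2-2 alone orange, the other 66 grey, and the dashed line marks equality. atp9 and atp8 rose most among mitochondrially encoded genes with a named product, ccmC fell in both lines, and changes of both lines together spanned log2 -1.27 to 3.00.

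The mean of both lines against the wild type asks for their common effect. Here 145 genes rose and 71 fell (216 of 20294), 70 of them by at least 2-fold, and 38 of the 216 were mitochondrially encoded (37 higher), 3 plastid-encoded and 175 nuclear. nad7 rose by log2 1.26 (adjusted p = 0.000519), atp6-1 by 1.42 (4.87e-05), atp9 by 1.87 (8.80e-05), atp1 by 1.07 (0.000519) and rps12 by 1.35 (0.00243). AT2G47780, LTP4 and CAT2 also passed this test, although their changes in clpp2-1 did not and the clpp2-1 libraries of AT2G47780 and CAT2 overlapped the wild type. CAT2 lost its call (adjusted p = 0.0126) without wt 1 (0.0618) or wt 3 (0.0670). The called lists were the mitochondrially encoded subunits of complexes III, IV and V (median 0.86, 8 of 10 higher and 8 adjusted over the list alone, adjusted p = 8.61e-15), complex I (0.47, 5 of 13 higher; adjusted over the list alone, 9 higher and 1 lower; 3.43e-07), and ribosomal and cytochrome c maturation genes (0.31, 5 of 14 higher and 1 lower; adjusted over the list alone, 7 and 1; 0.000872). They also included the plastid-encoded photosystem genes (0.34, 0.000591), nuclear-encoded subunits of complexes II to V (0.05, 0.0126), proteases and chaperones (0.11, 0.0309) and import (0.07, 0.0309). The remaining ones were photorespiration (0.15, 0.0381), light-harvesting (0.20, 0.00610), the chloroplast Clp protease (0.10, 0.00324), glucosinolate synthesis (-0.11, 0.0381) and floral markers (-0.38, 0.0344). The 6 mutant libraries lay beyond the 3 wild-type libraries, by mean deviation, for the 3 mitochondrially encoded lists and overlapped them for the other 9. None of these 12 calls held with an estimated correlation, where the adjusted p was 0.441 for complexes III, IV and V and 0.620 or 0.654 for the others.

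Several of these calls rested on single libraries. Proteases were lost without wt 1 (0.0662), wt 3 (0.0531) or clpp2-1 2 (0.0505), import without wt 1 (0.115), wt 3 (0.0622) or clpp2-1 2 (0.0552). Photorespiration was lost without wt 1 (0.0603), wt 3 (0.299), clpp2-1 2 (0.0742), clpp2-2 2 (0.0617) or clpp2-2 3 (0.0534), and light-harvesting (0.256) and the chloroplast Clp protease (0.0577) without wt 3. Glucosinolates were lost without wt 3 (0.233), clpp2-1 3 (0.0796), clpp2-2 1 (0.126) or clpp2-2 3 (0.0534), and floral markers without wt 2 (0.170) or wt 3 (0.0622). The number of genes called for the mean was 102 with the replicate block, and it was 77 without wt 1, 2168 without wt 2, 67 without wt 3, 132 and 94 without clpp2-1 2 and 3, and 120, 77 and 105 without clpp2-2 1, 2 and 3.

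**Figure D4:**
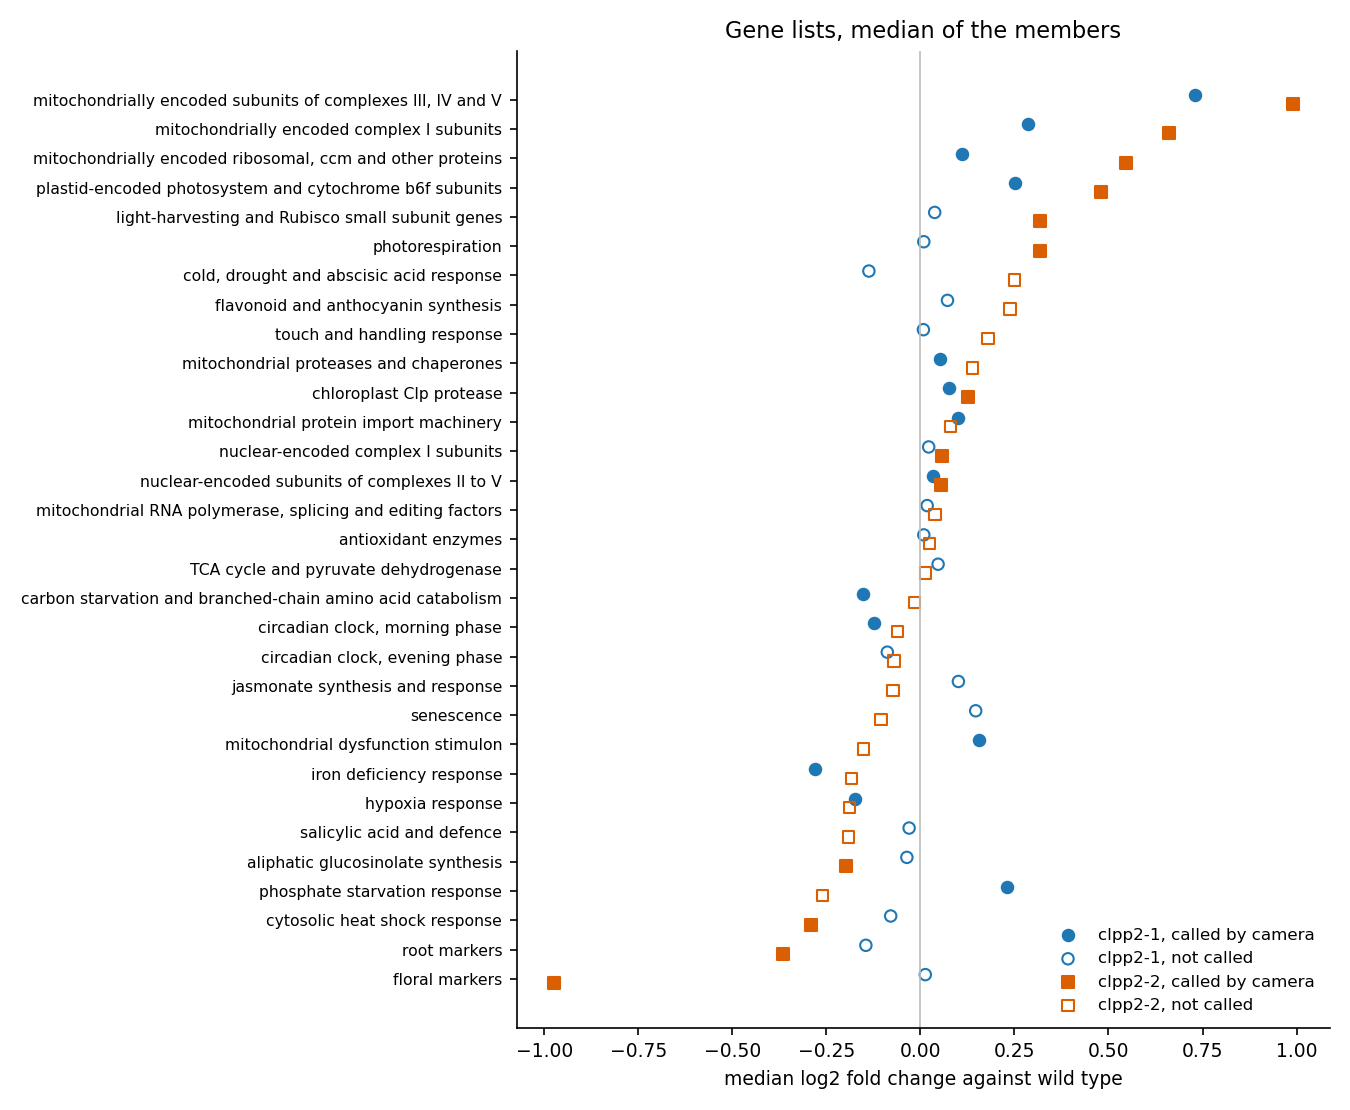
Median log2 fold change against wild type of 31 gene lists (seed storage markers, at -3.25 and -7.14, are left out) in clpp2-1 (circles) and clpp2-2 (squares); filled symbols mark lists called with the preset correlation. The mitochondrially encoded respiratory lists lie furthest above 0, at 0.73 and 0.99 for complexes III, IV and V, and floral markers lie lowest, at -0.97 in clpp2-2.

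The direct comparison of clpp2-2 with clpp2-1 asks whether the lines differ. Between them 475 genes were higher and 331 lower in clpp2-2 (806 of 20294), 199 by at least 2-fold; 801 of the 806 were nuclear and 5 mitochondrially encoded (5 higher). AT2G47780 was log2 3.76 higher in clpp2-2 (adjusted p = 0.000654), AT3G44006 6.27 (0.000330), COR15B 2.50 (0.000920), SEN1 2.62 (0.000920) and CAT2 1.13 (0.000546). LTP4 was lower by log2 -2.52 (0.00184) and SEP3 by -1.24 (0.00293). AT5G01990, lower in clpp2-1 alone, differed by log2 0.71 (adjusted p = 0.00281), and AT3G09360 was at least 76.1-fold higher in clpp2-2 (0.00244). atp9 (log2 -0.06, adjusted p = 0.781), atp8 (-0.16, 0.631), atp6-1 (0.10, 0.446) and atp1 (0.25, 0.125) did not pass the test between the lines. The count was 1463 without wt 2, 326, 373 and 199 without clpp2-1 1, 2 and 3, and 291, 171 and 209 without clpp2-2 1, 2 and 3.

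Between the lines 14 lists were called, 9 higher and 5 lower in clpp2-2, and 0 with an estimated correlation (adjusted p from 0.357 to 0.750). By mean deviation the libraries of the lines overlapped for 5 of the 14: complex I, complexes III, IV and V, plastid-encoded photosystem genes, the chloroplast Clp protease and glucosinolates. The mitochondrially encoded lists were higher in clpp2-2, with medians of 0.29 for complex I (adjusted p = 0.00161), 0.20 for complexes III, IV and V (0.0198; lost without clpp2-1 1, 0.195, or clpp2-2 1, 0.0684) and 0.31 for ribosomal and cytochrome c maturation genes (0.000450, 2 of 14 higher, 3 adjusted over the list alone). Cold, drought and abscisic acid genes had a median of 0.40 (0.00320, 2 of 12 higher, 5 adjusted over the list alone), photorespiration genes 0.30 (0.00161) and light-harvesting genes 0.24 (0.00140). The stimulon had a median of -0.28 (0.00399; adjusted over the list alone, 6 of 21 lower), phosphate starvation genes -0.40 (0.00217, 2 of 11 lower, 2 adjusted over the list alone), heat shock genes -0.33 (0.00452) and floral markers -1.24 (0.00946). Touch and handling genes (0.33, 0.0254) lost their call without clpp2-1 2 (0.0737), clpp2-2 1 (0.0732) or clpp2-2 3 (0.0955). Plastid-encoded photosystem genes (0.21, 0.0308) lost theirs without clpp2-1 1 (0.351), clpp2-1 3 (0.0685) or clpp2-2 2 (0.0755). The chloroplast Clp protease (0.09, 0.0352) lost it without clpp2-1 1 (0.154), clpp2-1 3 (0.117), clpp2-2 2 (0.0699) or clpp2-2 3 (0.0535), as did glucosinolates (-0.16, 0.00946) without clpp2-2 1 (0.120). The test fry, which asks whether a list's genes move on balance one way and compares them with no other genes, called 3 lists in clpp2-1, 7 in clpp2-2, 4 for the mean of both lines and 5 between the lines.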

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

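The lines carry mutations of the same gene and share a rise of part of the mitochondrial transcripts, and of the 806 genes that differ between them 801 are nuclear, among them COR15B, CAT2 and SEP3. The tests of explanations below were chosen after the results were seen.

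A difference between the lines was found by direct test for 806 genes. Among the named genes, those higher in clpp2-2 were ATMG01220 (log2 0.43), AT3G56210 (0.25), ATMG00030 (0.39), AT5G01990 (0.71), AT3G44006 (6.27), QQS (3.35), IAA20 (3.34), AT2G47780 (3.76), RBCS2B (0.93), COR15B (2.50), COR15A (0.94), WRKY40 (1.63), ERF5 (1.44), ZAT12 (0.59), SEN1 (2.62) and CAT2 (1.13). AT3G09360 was at least 76.05-fold and AT1G73350 at least 53.71-fold higher. Those lower in clpp2-2 were AT3G02400 (log2 -3.94), LTP4 (-2.52), AT4G12520 (-2.98), AT2G33170 (-2.55), PR2 (-1.27), PEPC1 (-1.66), SPX3 (-1.47) and SEP3 (-1.24), with AT1G72250 at least 27.75-fold and AT3G54930 at least 18.81-fold lower.

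Leaving out 1 library ended several of these calls, and the highest adjusted p and its library were ATMG01220 0.127 (clpp2-2 2), AT3G56210 0.0844 (clpp2-2 2), ATMG00030 0.115 (clpp2-1 3), QQS 0.127 (clpp2-2 2), IAA20 0.131 (clpp2-1 3), AT3G02400 0.0597 (clpp2-1 3), AT4G12520 0.135 (clpp2-2 2), AT2G33170 0.0982 (clpp2-2 3), RBCS2B 0.0686 (clpp2-1 3), PR2 0.109 (clpp2-1 3), COR15A 0.0684 (clpp2-1 3), WRKY40 0.0512 (clpp2-1 3), ERF5 0.0560 (clpp2-2 2), ZAT12 0.106 (clpp2-2 3), PEPC1 0.129 (clpp2-2 2) and SPX3 0.129 (clpp2-2 2).

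With the preset correlation, 14 lists also differed between the lines, but 0 were called with an estimated correlation (adjusted p from 0.357 to 0.750). The 14 lists, each with its median, were mitochondrially encoded complex I (0.295), complexes III, IV and V (0.196) and ribosomal and cytochrome c maturation genes (0.307), plastid-encoded photosystem genes (0.206), the stimulon (-0.283), photorespiration (0.297), light-harvesting (0.241), the chloroplast Clp protease (0.091), heat shock (-0.328), cold (0.403), touch (0.329), glucosinolates (-0.157), phosphate starvation (-0.398) and floral markers (-1.243). The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 806 genes and the highest other 2, and 14 lists against 15.

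Mitochondrially encoded genes were called in both lines in the same direction 27 times. A uniform rise of all mitochondrial transcripts is argued against, since 45.7% of the 116 genes lay more than 3 SE from their median. Organelle DNA in the mutant libraries is argued against as the only source, since 82.1% of 28 single-copy protein genes gained less than 10% of what atp9 gained per kilobase. The gain of atp9 was the largest, at 161.5 CPM per kilobase. The next was 36.8 in nad3 and the lowest -2.86 in ccmC, where DNA would add alike to each gene. Reads moved from nuclear copies are argued against, since the summed CPM of those copies rose by 15.9. In 1 of 100 splits, the real one, the count reached 27 (highest other 23, in a split that keeps the wild-type libraries together). This is the smallest share that 100 splits allow, and it argues against a random grouping for the fit without the replicate block. The margin over 23 was narrow, since the count asks mainly whether the wild-type libraries differ from the rest. With the block in the clpp2-1 comparison 18 of the 27 were called in both lines, and the splits were not run with it. A change in the synthesis or stability of particular mitochondrial transcripts without CLPP2 may remain as a hypothesis, which no test here addressed.

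The count of 2044 genes in clpp2-2 is argued against as GC content or exon length bias, since 1946 were called with those trends removed, and as the work of a single library, since at least 502 were called without any 1 (without clpp2-2 2). Fewer roots in clpp2-2 samples are argued against as the general cause of changes of at least 2-fold, since the root markers' median was -0.364. Single genes are not covered, as the markers ranged from log2 -1.11 to 1.71. For the smaller changes fewer roots cannot be told apart from other causes, since 17 of 18 root markers lay below 0. The 10 splits are too few for a share under 0.05, with 2044 genes against 1 in the highest other, and 13 lists against 15. A second mutation in the line, or a difference in culture or stage, could also be involved and was not tested.

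Counts that switched to 0 in whole genotypes, as in AT4G36850, AT3G09360, AT1G73350 and AT1G72250, may be an effect of counting and not of genotype: random placement of the zeros matched a genotype in as many genes with probability 0.272. Reads assigned to another transcript of the gene are a candidate explanation, since 97.4% of the 386 such genes have 2 or more annotated transcripts, against 40.7% in random sets. They would change the count of a gene only if that count left out some of its transcripts, which was not tested. Reads assigned to a near-identical gene are argued against as the general cause, since 4.66% have such a copy.

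For clpp2-1 the 10 splits are also too few, with 36 genes against 3 in the highest other and 14 lists against 13; of the 4 splits that part the 3 pairs of same-numbered libraries, the others called 0, 1 and 3 genes. For the mean of both lines 2 of 100 splits called as many genes, the real one (216) and another (1742), in fits without the block. Few splits reached the real count, but a wrong grouping exceeded it. The count therefore cannot tell genotype from another structure of the libraries. The split with 1742 took wt 1, wt 3 and clpp2-1 3 as the wild type, and a split outside the 100 with wt 1, wt 3 and clpp2-1 1 called 2432. The other 4 splits of the wild-type and clpp2-1 libraries that keep wt 1 as the wild type and move wt 2 called 35, 17, 31 and 20. Each of these also moves wt 3 or clpp2-1 2, so none isolates wt 2. Splits that move wt 1 and keep wt 2 called 60 (with wt 2, wt 3 and clpp2-1 2 as the wild type) and 9 (with wt 2, wt 3 and clpp2-1 3). With wt 2 left out and the true genotypes kept, 2168 genes were called. For the lists of the mean, 26 of 100 splits called as many (12, highest other 18), so chance is not excluded. Genes called in both lines reached 33 in 1 of 100 splits, the real one (highest other 26, with the wild-type libraries kept together). This argues against a random grouping for the fit without the block, with which 22 were called.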

How the results depend on the processing

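The DESeq2 size factors, no filter, limma-voom, library sizes without organelle genes and the GC and length correction left each count of genes within 1.5-fold. Organelle genes, among them 27 of the 36 called in clpp2-1, stayed in these tests. The GC and length correction was not applied to them. The DESeq2 test called 92 genes in clpp2-1, 3410 in clpp2-2, 1198 for the mean of both lines, 1775 between the lines and 64 in both lines; in simulated data it made more false calls. The replicate block gave 23 for clpp2-1, 102 for the mean and 513 between the lines. In clpp2-1 it ended 13 calls of genes and added none; those not given with the results above were matR (adjusted p = 0.0988), ATMG00610 (0.117), ATMG00690 (0.0817), ATMG01130 (0.181) and ATMG01210 (0.104). Only the groups compared gave 21, 1216, 1494 between the lines and 19 in both. Without wt 1 and clpp2-1 1, chosen after seeing the data, there were 23, 727, 94 for the mean, 336 between the lines and 19 in both, with fewer libraries. The 2-fold threshold left 382 in clpp2-2, 70 for the mean and 199 between the lines. Leaving out 1 library gave 23 (wt 1) to 63 (wt 2) in clpp2-1, 502 (clpp2-2 2) to 4242 (wt 2) in clpp2-2, 67 (wt 3) to 2168 (wt 2) for the mean, 171 (clpp2-2 2) to 1463 (wt 2) between the lines and 20 (wt 1) to 57 (wt 2) in both; the cause was not tested.

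An estimated correlation called 0 lists in each of the 4 contrasts, and fry 3 in clpp2-1, 7 in clpp2-2, 4 for the mean and 5 between the lines. Leaving out 1 library gave 4 to 16 lists in clpp2-1, 10 to 16 in clpp2-2, 8 to 18 for the mean and 12 to 17 between the lines. The log2 ratio of the mitochondrial share in clpp2-2 was 0.857 with protein-coding genes only, against 0.988. CLPP2 kept its direction and call under each alternative run.

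Of the genes not called for the mean of both lines, LHY turned to 0.0052 without wt 1 and clpp2-1 1 and ran from -0.37 to 0.054 (without wt 1) with 1 library left out, CCA1 from -0.0017 (without wt 3) to 0.15, WRKY53 turned to 0.16 and ran from -0.51 to 0.15 (without wt 1), and PI turned to 0.38 with limma-voom and 0.10 with the block and ran from -0.91 to 0.19 (without wt 3); the cause was not tested. Of 208 called results of named genes, 190 were kept by limma-voom, 207 by DESeq2, 162 by the block and 136 without wt 1 and clpp2-1 1. In simulated data edgeR found 43.3 and 49.3% of the genes changed 1.5-fold in clpp2-1 and clpp2-2, and DESeq2, with more false calls, 64.2 and 65.7%.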

Other observations

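MLS and ICL, which encode enzymes of the glyoxylate cycle, were higher in clpp2-2; the cycle was not tested as a group. The genes here were chosen after their values were seen, and no explanation was tested for them. MLS, malate synthase, stood at 62.0 ± 21.4 CPM in the wild type, 86.1 CPM in clpp2-1 and 593.6 ± 98.6 CPM in clpp2-2 (log2 3.26, adjusted p = 0.000519; against clpp2-1 2.79, adjusted p = 0.00150). ICL (AT3G21720), isocitrate lyase, stood at 4141 ± 200.2, 4333 ± 821.4 and 10640 ± 1810.0 CPM (log2 1.36, adjusted p = 0.00219; against clpp2-1 1.30, adjusted p = 0.00440), and was the most abundant gene of clpp2-2 1 at 1.27% of its counts.

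The cold response regulator CBF2 rose in clpp2-2 from 0.458 to 4.16 CPM (adjusted p = 0.00130) and AGO9, an Argonaute gene, from 0.513 to 4.85 CPM (adjusted p = 0.00148). MRD1 rose from 7.47 to 77.3 CPM (adjusted p = 2.75e-05), and HEI10, whose annotated span overlaps that of MRD1 on chromosome 1, from 1.33 to 7.03 CPM (adjusted p = 0.000192).

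The difference of wt 2 from the mean of wt 1 and wt 3 correlated across 12677 genes with the difference between clpp2-2 and clpp2-1 (0.345; genes are not independent replicates), against 0.048 for the difference of wt 1 and wt 3.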
